A study of Mus musculus with 16 samples.

How the data were processed

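RNA of 16 mouse liver samples was sequenced as 1 library each, 4 per group. The deposited tables give, per the file headers, expected counts (estimated reads or fragments per gene, not normalised) and FPKM (fragments per kilobase of transcript scaled to the library's total, as calculated by the authors). HISAT2 was the aligner per the submitters' processing notes, without a version, and the counting program, genome build and annotation are not given in the sources used here. Between 25.3% and 27.2% of the expected counts in a library had decimals other than 0 as given, without a tolerance, and genes below an FPKM of 0.01 were not listed, so unlisted genes were taken as 0. The tables held 17436 entries, of which 26 were named by a transcript and were summed into their gene, leaving 17410 genes. NCBI gene numbers were matched to a GRCm38.p6 gene table for 17371 of them, which served for names and gene order only. In 1 library 22 symbols had been turned into dates and were restored by gene number. The libraries held 21254937 to 40327264 expected counts, and between libraries of a group the chi-square of the counts per degree of freedom was 17.2 to 240.3 over genes with at least 20 counts in the pair.

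Groups were taken from the sample labels, which number the replicates from 9 to 24 without stating outright that each is a separate animal. The p-values measure the spread between these samples, which would be technical if they were not. Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalisation, quasi-likelihood F test, two-sided), in 2 separate fits of 8 libraries: LKO_NASH against WT_NASH over 12786 genes, and Ad_Chrebpa_HFLMCD against Ad_GFP_HFLMCD over 13658 genes. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called, without a minimum fold change. Biological coefficients of variation were 0.221 and 0.126. All log2 fold changes are from edgeR unless another tool is named, and FPKM is given as the mean with the SD of 4 livers.

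Before the data were examined, 31 gene lists were fixed, with 543 distinct genes of which 534 were found. They covered ChREBP targets, lipogenesis and triglyceride synthesis, glycolysis and fructolysis, gluconeogenesis, fatty acid oxidation and PPARα, cholesterol synthesis, bile acids and cholesterol efflux, lipid droplets and uptake, lipoprotein secretion, inflammation, the acute phase, interferon response, fibrosis and matrix, endoplasmic reticulum and integrated stress, oxidative stress with Nrf2 and the pentose phosphate pathway, p53 and apoptosis, the cell cycle, xenobiotic metabolism, oxidative phosphorylation, the circadian clock and sex-biased liver genes. The remaining lists held markers of hepatocytes, macrophages and Kupffer cells, T and NK cells, B and plasma cells, neutrophils, sinusoidal endothelium, stellate cells, cholangiocytes, erythroid cells, and adipocytes with pancreas. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The rule for named genes, also fixed then, took Mlxipl, Mlx, Mlxip, Srebf1, Pklr, Txnip and Fgf21, the 6 largest differences in each direction among called genes with a mean FPKM of at least 1 in the higher group and no overlap between groups, and up to 3 called members of each list with the lowest adjusted p. Predicted genes and pseudogenes were left out of the largest differences. Genes called with opposite signs in both comparisons were to be named as well. Of the genes this rule took, 1 is not reported here.

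Overlaps between comparisons were tested with Fisher's exact test in SciPy 1.17.1. The correlation of fold changes was set against 100 regroupings within each experiment. Gene Ontology process terms in the deposited tables with 10 to 500 tested genes were tested by one-sided Fisher's exact test against all tested genes, adjusted over 1615 terms. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

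Alternatives fixed beforehand were DESeq2 size factors, no filter, a mean FPKM of at least 1, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) with and without a filter and on log2(FPKM + 0.1), all 16 libraries in 1 fit, a fold change of at least 1.5, and leaving out each liver in turn. Chosen after seeing the data were keeping transcript entries separate, leaving out blocks of clustered calls, leaving out livers 19 and 21 together, and repeating the term test under other settings. The gene test was also tested on simulated data with the depths and spread of these libraries, in which genes were drawn independently of each other. In the NASH simulation 12% of genes changed 1.5-fold, 55.1% of those changed 2-fold, 85.7% of those changed 3-fold and 98% of those changed 4-fold were called in the right direction, and 2.3% of 129 calls were unchanged genes. In the HFLMCD simulation these shares were 52%, 83.7%, 93.9% and 100%, and 6% of 184 calls were unchanged genes.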

Results

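RNA sequencing was done on 16 mouse liver samples in 4 groups of 4, arranged as 2 experiments on ChREBPα, an isoform of the carbohydrate-responsive transcription factor that the gene Mlxipl encodes. In the deletion experiment, Chrebpα-flox/flox mice received an adeno-associated virus that expressed GFP (WT_NASH, livers 17 to 20) or Cre recombinase (LKO_NASH, livers 21 to 24) from the hepatocyte promoter TBG. They ate a NASH diet, with 40% of calories from fat, 20% from fructose and 2% cholesterol, for 12 weeks. In the overexpression experiment, wildtype mice received adenovirus for GFP (Ad_GFP_HFLMCD, livers 9 to 12) or Chrebpα (Ad_Chrebpa_HFLMCD, livers 13 to 16). Their choline-free HFLMCD diet had 45% of calories from fat and 0.1% added methionine. The diet began at 2 months of age and lasted 3 weeks, and the virus was given 1 week before dissection. The total of expected counts per liver ran from 21254937 to 40327264 in WT_NASH, 21569511 to 32110154 in LKO_NASH, 32131999 to 36163207 in Ad_GFP_HFLMCD and 29640300 to 33996245 in Ad_Chrebpa_HFLMCD. The 10 most counted genes took 14.59% to 20.35% of the counts of a liver.

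Mlxipl (NCBI gene 58805) was the gene targeted in both experiments, and its level was similar in the groups of each. Its FPKM was 50.1, 77.5, 80.4 and 56.4 in livers 17 to 20 (WT_NASH, mean 66.1 ± 15.1 SD, n = 4). The livers labelled LKO_NASH had 47.5, 100.1, 85.1 and 72.9 (livers 21 to 24, mean 76.4 ± 22.3 SD, n = 4). In the Ad_GFP_HFLMCD livers 9 to 12 it was 48.5, 46.8, 39.0 and 40.7 (mean 43.7 ± 4.61 SD, n = 4). The livers labelled Ad_Chrebpa_HFLMCD had 46.6, 45.2, 44.7 and 47.8 (livers 13 to 16, mean 46.1 ± 1.41 SD, n = 4). The edgeR log2 fold change was 0.05 in LKO_NASH (95% interval -0.54 to 0.65, adjusted p = 0.916) and 0.15 in Ad_Chrebpa_HFLMCD (-0.04 to 0.33, adjusted p = 0.241). These gene totals test the labels weakly, because the deleted exon is not given in the sources used here and the vector sequence may not be counted as Mlxipl. Among the partners and relatives of ChREBP, Mlx had log2 fold changes of -0.36 and -0.27 in the deletion and overexpression experiments (adjusted p = 0.356 and 0.0652). The overexpression value for Mlx passed by DESeq2 (adjusted p = 0.028), on log2(FPKM + 1) (0.0238) and by edgeR without liver 10 (0.0493) or liver 14 (0.0312). Mlxip, the paralogue also called MondoA, had 0.22 and 0.11 (adjusted p = 0.384 and 0.687), the latter 0.01 without liver 12 and 0.25 without liver 10.

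**Figure D1:**
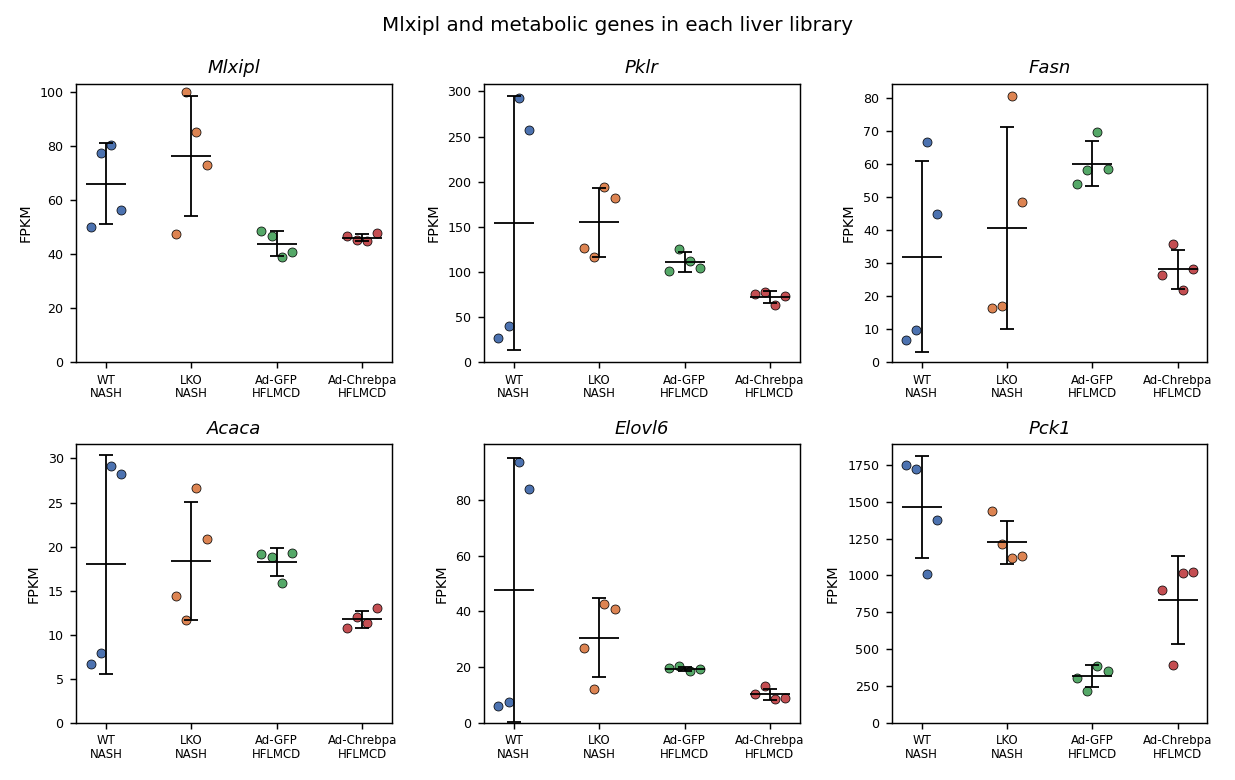
FPKM of Mlxipl, Pklr, Fasn, Acaca, Elovl6 and Pck1 in each of the 16 livers by group, with horizontal lines for the group mean and bars for 1 SD (n = 4). Mean Fasn was 60.0 in Ad_GFP_HFLMCD and 27.97 in Ad_Chrebpa_HFLMCD, while Mlxipl overlapped between the groups of each experiment and Pklr spread from 26.9 to 293 within WT_NASH.

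The deletion experiment asked what loss of hepatocyte ChREBPα does in a liver under NASH diet. In the livers labelled LKO_NASH, genes of macrophages, interferon response, inflammation, matrix and fatty acid oxidation shifted up as groups against WT_NASH, and acute-phase and hepatocyte genes shifted down. Macrophage markers had a median log2 fold change of 0.71, interferon response genes 0.54, inflammation genes 0.56, fibrosis and matrix genes 0.46 and fatty acid oxidation genes 0.21, against -0.81 for acute-phase genes and -0.27 for hepatocyte markers. These lists passed camera with its preset correlation, and with an estimated correlation their adjusted p was 0.403 to 0.412. No single gene passed: edgeR called 0 higher and 0 lower among 12786 tested, with the lowest adjusted p at 0.242 for Acot2, 985 genes higher and 752 lower at an unadjusted p below 0.05, 0 by limma-voom, and 90 higher and 68 lower by DESeq2. Without liver 21 edgeR called 166 genes higher and 254 lower, and without any other single liver 0. On the first principal component, with 42.8% of the variance, livers 22 to 24 lay at 28.57 to 35.41, the WT_NASH livers at -41.68 to 3.02 and liver 21 at -27.09. Of the 29 fixed lists tested, 15 passed camera with its preset correlation, 0 with an estimated correlation and 0 by the directional test of fry. For the members named in this comparison that are not Mlxipl's partners or fixed genes, the choice was made after their values were seen, as the lowest p of each passing list, and the counts of members called over all tested genes were 0 in every list.

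Genes of fatty acid oxidation and of lipid droplets were part of the upward shift in LKO_NASH livers. Of 32 fatty acid oxidation and PPARα genes, 27 had a positive log2 fold change (camera adjusted p = 1.22e-05; adjusted p = 0.403 with an estimated correlation), and 2 were higher adjusted over the list alone. Acot2, a mitochondrial acyl-CoA thioesterase, had a mean FPKM of 4.91 ± 0.77 in WT_NASH and 12.9 ± 2.87 in LKO_NASH (SD, n = 4), a log2 fold change of 1.24 (SE 0.15). Its near-identical neighbour Acot1 had 0.86, with reads shared between the copies making the division of the counts uncertain, and Pdk4, which restrains pyruvate oxidation, had 1.58. Of 24 lipid droplet and uptake genes, 20 were positive (median 0.32, adjusted p = 0.000397; adjusted p = 0.403 with an estimated correlation; 0 adjusted over the list alone), among them the receptors Vldlr at 1.95 and Cd36 at 1.30 and the droplet coat gene Plin4 at 0.68. Without liver 21 the calls of Acot2 (adjusted p = 0.00957), Acot1 (0.0389) and Vldlr (0.0279) passed. Vldlr had a low level, with a mean FPKM of 0.17 in WT_NASH and 0.74 in LKO_NASH.

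Established ChREBP targets did not pass as a list in this comparison. The 26 target genes had a median of 0.01 on counts (camera adjusted p = 0.729). On log2(FPKM + 0.1) their median was 0.27, over the members that passed the FPKM filter. Pklr, the liver pyruvate kinase, had a log2 fold change of -0.10 (SE 0.67), with FPKM from 26.9 to 293 within WT_NASH. Srebf1, the insulin-responsive regulator of lipogenesis, had -0.11, Txnip 0.13 and the hepatokine Fgf21 0.25, with adjusted p of 0.910, 0.817 and 0.826. These values moved with single livers: Pklr had -0.45 without liver 17 and 0.42 without liver 19, and Srebf1 -0.40 and 0.22 without the same livers. Txnip had -0.07 without liver 24 and 0.34 without liver 23, and Fgf21 -0.01 without liver 17 and 1.14 without liver 20. Other lists that did not pass were lipogenesis (median 0.23, adjusted p = 0.052), glycolysis and fructolysis (0.11, 0.223), gluconeogenesis (-0.05, 0.386), cholesterol synthesis (0.32, 0.0721), bile acid and cholesterol efflux (0.05, 0.874), lipoprotein secretion (-0.04, 0.822), xenobiotic metabolism (0.20, 0.368), oxidative phosphorylation (0.07, 0.495), the circadian clock (0.03, 0.883) and sex-biased genes (-0.04, 0.142). Adjusted over the list alone, 1 bile acid gene was lower, 1 lipoprotein gene higher and 1 sex-biased gene lower, and 0 members of the other lists passed. On log2(FPKM + 1) the median of all genes lay 0.136 higher than on counts in this comparison, and 0.146 higher with a pseudocount of 0.1. With the pseudocount of 0.1 the gluconeogenesis, lipoprotein and sex-biased medians turned positive, over the members that passed the FPKM filter.

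The inflammation and matrix lists shifted up in LKO_NASH livers together with the marker lists of macrophages, T and NK cells and endothelium. The 20 macrophage and Kupffer cell markers had a median of 0.71 (adjusted p = 4.19e-06; adjusted p = 0.403 with an estimated correlation), with Itgax at 1.54, Adgre1 at 0.94 and Cd68 at 0.88. The 7 tested T and NK cell markers had a median of 0.92 (adjusted p = 0.00691; adjusted p = 0.403 with an estimated correlation), with Cd3e at 1.45, a list call that ended without livers 19 and 21 together (adjusted p = 0.162). The 12 sinusoidal endothelium markers had a median of 0.41 (adjusted p = 0.000206; adjusted p = 0.412 with an estimated correlation), with Gpr182 at 0.59. Of 15 inflammation genes, 13 were positive (adjusted p = 4.19e-06; adjusted p = 0.403 with an estimated correlation), including the chemokines Cxcl10 at 1.65 and Ccl5 at 1.46 and the adhesion molecule Vcam1 at 0.73. Of 23 interferon response genes, 22 were positive (adjusted p = 2.03e-06; adjusted p = 0.403 with an estimated correlation), with Oasl1 at 0.54 and Gbp3 at 1.08. Liver 21 had 8.01 FPKM of Gbp3 against 3.08 to 3.66 in livers 22 to 24, and without it the log2 fold change was 0.60. Of 25 fibrosis and matrix genes, 23 were positive (adjusted p = 4.19e-06; adjusted p = 0.403 with an estimated correlation), with the collagens Col1a1 at 1.08 and Col3a1 at 1.01 (0.70 and 0.67 without liver 24) and the cytokine Tgfb1 at 0.76, which passed without liver 21 (adjusted p = 0.0474). Adjusted over the list alone, 8 inflammation genes were higher and 1 lower, 2 T and NK genes and 1 matrix gene were higher, and 0 macrophage, endothelium and interferon genes passed. Cd3e and Itgax had low levels, with mean FPKM of 0.13 and 0.30 in WT_NASH and 0.39 and 0.99 in LKO_NASH.

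Proliferation and stress lists also moved in LKO_NASH livers. The 21 cell cycle genes had a median of 0.41 (adjusted p = 0.000287; adjusted p = 0.403 with an estimated correlation), with the proliferation markers Mki67 at 1.87 and Top2a at 1.43 and the cyclin Ccne1 at -0.76. Of these, 2 were higher and 1 lower adjusted over the list alone, and Mki67 passed without liver 21 (adjusted p = 0.0314). Mki67 and Top2a had low levels, with mean FPKM of 0.07 and 0.11 in WT_NASH and 0.28 and 0.35 in LKO_NASH. The cell cycle list call ended without livers 19 and 21 together (adjusted p = 0.0764). Of 21 Nrf2 and pentose phosphate genes, 19 were positive (median 0.37, adjusted p = 3.29e-05; adjusted p = 0.255 with an estimated correlation), with the quinone reductase Nqo1 at 1.03. Gstm1 at 0.69 and Gsta4 at 0.59 belong to families of similar sequence and are uncertain, and Gsta4 passed without liver 21 (0.0455). The 16 p53 and apoptosis genes had a median of 0.28 (adjusted p = 0.0381; adjusted p = 0.479 with an estimated correlation), with the stress cytokine Gdf15 at 1.46 (0.97 without liver 24) and Bbc3 at 0.55. That call ended without liver 18 (adjusted p = 0.131), 19 (0.232), 21 (0.424) or 24 (0.0532), and without 19 and 21 together (0.76). The Nrf2 and p53 lists had 0 members passing adjusted over the list alone.

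The acute-phase, hepatocyte marker and endoplasmic reticulum stress lists shifted down. Of 19 acute-phase genes, 17 were negative (median -0.81, adjusted p = 5.55e-06; adjusted p = 0.412 with an estimated correlation), including Steap4 at -1.09, Saa4 at -1.04 and Itih4 at -0.82 (-0.52 without liver 17). The 15 hepatocyte markers had a median of -0.27 (adjusted p = 0.001; adjusted p = 0.403 with an estimated correlation), with the plasma protein Ahsg at -0.66, the urea cycle enzyme Cps1 at -0.62 and Serpina1a, which shares reads with near-identical copies, at -0.58. The 20 genes of endoplasmic reticulum and integrated stress had a median of -0.28 (adjusted p = 0.0121; adjusted p = 0.504 with an estimated correlation), with the regulator Xbp1 at -0.75 and the chaperone Hsp90b1 at -0.47 but Atf3 at 0.98 (0.55 without liver 24). That call ended without liver 18 (adjusted p = 0.0701) or 23 (0.169). Without liver 21, Steap4 (adjusted p = 0.0337), Xbp1 (0.0239) and Ahsg (0.0425) passed. Adjusted over the list alone, 1 hepatocyte marker was lower and 0 genes of the other lists passed.

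Of the remaining cell markers, 6 erythroid genes had a median of 0.49 in LKO_NASH livers (adjusted p = 0.0267; adjusted p = 0.504 with an estimated correlation), with the β-globin Hbb-bt at 0.58 and the near-identical Hba-a1 and Hba-a2 at 0.54 and 0.51. Hbb-bt, Hba-a1 and Hba-a2 had 0.37, 0.34 and 0.32 without liver 20 and 0.97, 0.84 and 0.76 without liver 17. The erythroid call ended without liver 18 (adjusted p = 0.0701), 19 (0.0557), 20 (0.168), 22 (0.0863) or 24 (0.0873), and without 19 and 21 together (0.0764). Neutrophil (median 0.31, adjusted p = 0.565), stellate (0.06, 0.773) and cholangiocyte markers (-0.06, 0.822) did not pass, with 0 members adjusted over the list alone. On log2(FPKM + 0.1) the neutrophil median was -0.02 and the cholangiocyte median 0.07, over the members that passed the FPKM filter, which can be fewer. B and plasma cell markers (4 tested, median 0.39) and adipocyte and pancreas markers (2 tested, median 0.30) were too few for the list test. Altogether 12 of the 15 list calls were kept without each single liver.

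The overexpression experiment asked what added ChREBPα does in a liver under HFLMCD diet. In the livers labelled Ad_Chrebpa_HFLMCD, the lipogenesis and glycolysis lists shifted down by camera, with 4 of 23 and 5 of 19 members called lower and 2 and 0 higher. Fasn, the fatty acid synthase, went from a mean FPKM of 60.0 ± 6.78 to 27.97 ± 5.77 (SD, n = 4), Elovl6 from 19.4 ± 0.70 to 10.2 ± 2.06 and Pklr from 110.5 ± 10.9 to 72.3 ± 6.68. The lists of bile acid handling, xenobiotic metabolism, the acute phase, the circadian clock and fatty acid oxidation shifted up, with Abcc2, a canalicular export pump, going from 80.7 ± 4.00 to 129.5 ± 9.30. The cholangiocyte and cell cycle lists shifted down, with 4 of 9 and 3 of 23 members called lower. For these lists the adjusted p was 0.187 to 0.424 with an estimated correlation. Other genes were near absent in 1 of the groups, among them Corin with a mean FPKM of 7.01 in Ad_GFP_HFLMCD and 0.04 in Ad_Chrebpa_HFLMCD, and Camk2b with 0.04 and 3.62. Among 13658 genes edgeR called 676 higher and 434 lower, 917 of them by less than 2-fold, and 3625 had an unadjusted p below 0.05. The count was 376 higher and 223 lower without liver 11, 348 and 185 without liver 12, 340 and 185 without liver 13, 937 and 785 without liver 14, 400 and 209 without liver 15, and 263 and 137 without liver 16. Liver 14 stood apart from its group: its median position on genes chosen without it was 0.54, from the Ad_GFP_HFLMCD mean at 0 to the mean of the other Ad_Chrebpa_HFLMCD livers at 1, against 0.95 to 1.06 for livers 13, 15 and 16. On the first principal component, with 42% of the variance, it lay at 10.27 and those livers at 24.06 to 28.09. The share of higher calls was 60.9% on counts and 30.4% on log2(FPKM + 1). Of 30 fixed lists tested, 20 passed camera with its preset correlation, 12 the directional test of fry and 0 camera with an estimated correlation.

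**Figure D2:**
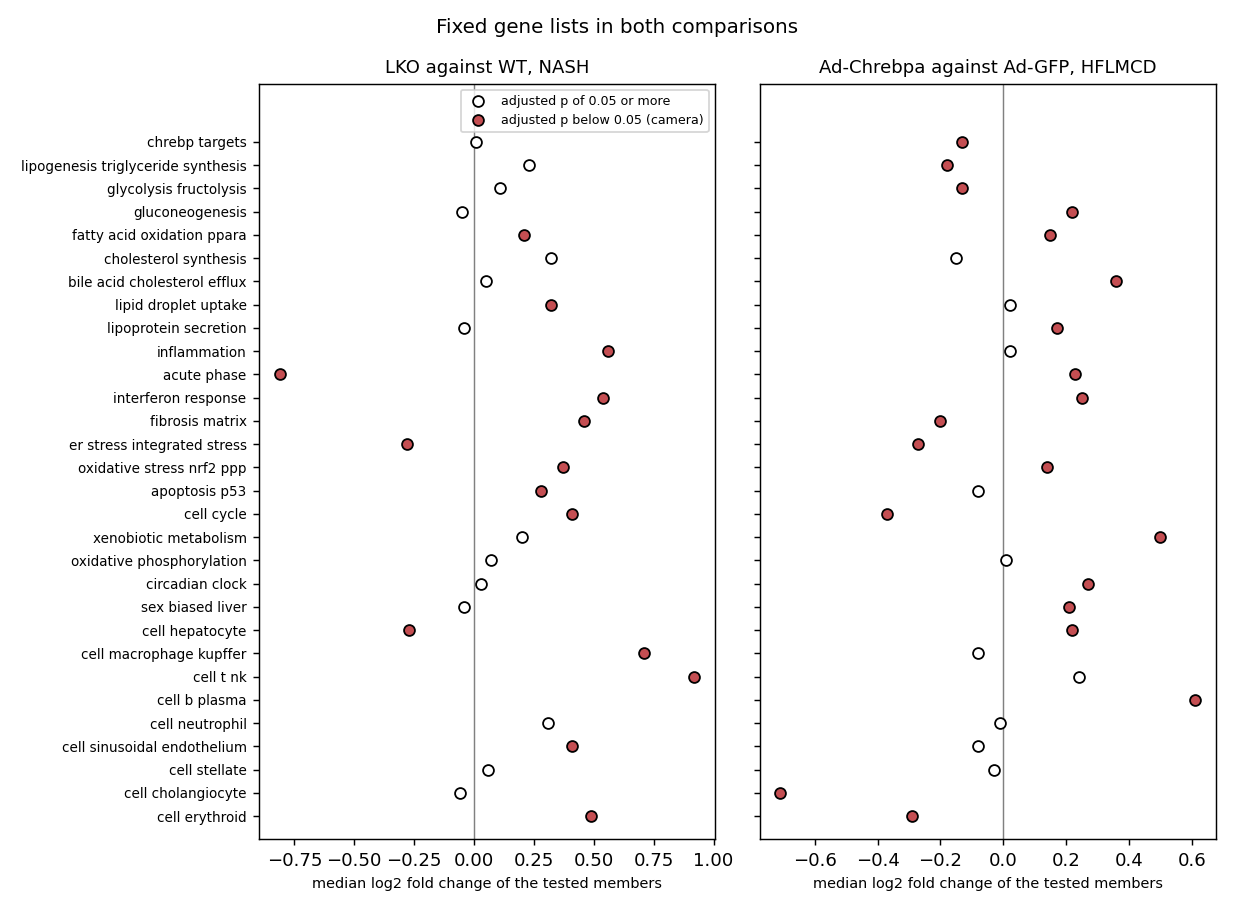
Median log2 fold change of the tested members of each fixed gene list in the LKO_NASH against WT_NASH and the Ad_Chrebpa_HFLMCD against Ad_GFP_HFLMCD comparisons, with filled points for an adjusted p below 0.05 by camera with a preset correlation of 0.01. Acute-phase genes had medians of -0.81 and 0.23 and cell cycle genes 0.41 and -0.37 in these comparisons. Interferon response genes had 0.54 and 0.25, and endoplasmic reticulum stress genes -0.28 and -0.27. With an estimated correlation 0 lists passed in either.

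The lists of ChREBP targets, lipogenesis and glycolysis shifted down in Ad_Chrebpa_HFLMCD livers, with most members not called. Of 26 ChREBP targets, 1 rose and 6 fell, with 2 higher and 9 lower adjusted over the list alone (median -0.13, camera adjusted p = 0.00741; adjusted p = 0.351 with an estimated correlation). Of 23 lipogenesis genes, 2 rose and 4 fell, with 2 and 8 adjusted over the list alone (median -0.18, adjusted p = 0.00526; adjusted p = 0.34 with an estimated correlation). Fasn had a log2 fold change of -1.03 (SE 0.14, adjusted p = 0.00371), the elongase Elovl6 -0.86 (SE 0.12, 0.00393) and Acaca, the acetyl-CoA carboxylase, -0.57 (SE 0.08, 0.00392). Pklr fell by 0.54 (SE 0.08, adjusted p = 0.00671), while Srebf1 had -0.54 without passing edgeR (0.0562). Srebf1 passed by DESeq2 (adjusted p = 0.00753), on log2(FPKM + 1) (0.0317) and by edgeR without liver 14 (0.0422). Of 19 glycolysis and fructolysis genes, 0 rose and 5 fell, with 1 and 5 adjusted over the list alone (median -0.13, adjusted p = 0.00741; adjusted p = 0.395 with an estimated correlation), among them Tkfc, the triokinase of fructose breakdown, at -0.68. The Tkfc call ended without liver 16 (adjusted p = 0.0562). Txnip had 0.35 (adjusted p = 0.347), or 0.59 without liver 10 and 0.21 without liver 15. Fgf21 had -2.37 (adjusted p = 0.132) with 243.8 FPKM in liver 11 and 14.4 to 19.4 in the other Ad_GFP_HFLMCD livers; its log2 fold change was -0.27 without liver 11. Of 24 cholesterol synthesis genes 0 rose and 3 fell, with 1 and 3 adjusted over the list alone, and the list did not pass (median -0.15, adjusted p = 0.0505); Dhcr7 was at -0.42.

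The bile acid, fatty acid oxidation and lipoprotein lists shifted up in Ad_Chrebpa_HFLMCD livers. Of 23 bile acid and cholesterol efflux genes, 10 rose and 0 fell, with 14 and 0 adjusted over the list alone (median 0.36, adjusted p = 1.32e-08; adjusted p = 0.187 with an estimated correlation). Abcc2 was at 0.75 (SE 0.07, adjusted p = 0.000654), the bile acid-CoA ligase Slc27a5 at 0.62 and the sterol 27-hydroxylase Cyp27a1 at 0.44. Of 32 fatty acid oxidation genes, 6 rose and 0 fell, with 12 and 0 adjusted over the list alone (median 0.15, adjusted p = 9.86e-05; adjusted p = 0.424 with an estimated correlation), among them Eci2 at 0.43 and Etfdh at 0.38, while the regulator Ppara at 0.49 lost its call without liver 16 (adjusted p = 0.0509). Of 17 lipoprotein genes, 5 rose and 1 fell, with 7 and 1 adjusted over the list alone (median 0.17, adjusted p = 0.0023; adjusted p = 0.351 with an estimated correlation), led by the hepatic lipase Lipc at 0.66 and the cholesterol acyltransferase Lcat at 0.56. Of 23 lipid droplet genes, 3 rose and 1 fell, with 4 and 2 adjusted over the list alone, while the list did not pass (median 0.02, adjusted p = 0.954); the lipase Pnpla2 was at 0.43 and Pparg at -0.59. Of 12 gluconeogenesis genes 1 rose and 0 fell, also adjusted over the list alone (median 0.22, adjusted p = 0.0238; adjusted p = 0.508 with an estimated correlation). That gene was Pck1, the committing enzyme of gluconeogenesis, with a mean FPKM of 314 ± 74.1 in Ad_GFP_HFLMCD and 831 ± 299 in Ad_Chrebpa_HFLMCD (SD, n = 4; log2 fold change 1.47), whose call ended without liver 16 (adjusted p = 0.0561). The list call ended without liver 10 (adjusted p = 0.121) or 13 (0.0794).

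The xenobiotic metabolism, clock and acute-phase lists also shifted up. Of 17 xenobiotic metabolism genes, 7 rose and 0 fell, with 11 higher and 2 lower adjusted over the list alone (median 0.50, adjusted p = 1.9e-06; adjusted p = 0.34 with an estimated correlation). Cyp2c29 was at 2.56, though reads are shared in the Cyp2c family, and Nr1i3, the constitutive androstane receptor, at 0.55. Of 16 clock genes, 6 rose and 0 fell, with 9 and 1 adjusted over the list alone (median 0.27, adjusted p = 0.00112; adjusted p = 0.34 with an estimated correlation), among them the repressor Nr1d1 at 0.85, whose call ended without liver 16 (adjusted p = 0.0513). Of 19 acute-phase genes, 8 rose and 0 fell, with 10 and 1 adjusted over the list alone (median 0.23, adjusted p = 7.35e-07; adjusted p = 0.34 with an estimated correlation), with the lipopolysaccharide-binding protein Lbp at 0.80 and the fibrinogen chain Fgb at 0.44, and Saa1 at 1.07 with reads shared with Saa2. Of 22 Nrf2 and pentose phosphate genes, 4 rose and 0 fell, with 8 and 1 adjusted over the list alone (median 0.14 and on FPKM 0.00, adjusted p = 0.0212; adjusted p = 0.424 with an estimated correlation), with the catalase gene Cat at 0.35, whose call ended without liver 11 (adjusted p = 0.0508). The Nrf2 list call ended without liver 9 (adjusted p = 0.0685) or 14 (0.139). Of 10 sex-biased genes 1 rose and 0 fell, with 4 and 2 adjusted over the list alone (median 0.21, adjusted p = 0.0311; adjusted p = 0.34 with an estimated correlation). The elongase Elovl3 was that gene, at 1.41, and the list call ended without liver 9 (adjusted p = 0.0742), 10 (0.055) or 14 (0.0501).

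Of the cell marker lists, 4 passed camera in Ad_Chrebpa_HFLMCD livers. Of 9 cholangiocyte markers, 0 rose and 4 fell, with 0 and 6 adjusted over the list alone (median -0.71, adjusted p = 6.14e-05; adjusted p = 0.351 with an estimated correlation), among them the chloride channel gene Cftr at -2.51 and the keratin Krt19 at -1.22. Of 15 hepatocyte markers, 4 rose and 0 fell, with 7 and 0 adjusted over the list alone (median 0.22, adjusted p = 0.00107; adjusted p = 0.424 with an estimated correlation), with the histidine ammonia-lyase gene Hal at 0.72. Of 7 B and plasma cell markers, 2 rose and 0 fell, also adjusted over the list alone (median 0.61, adjusted p = 0.00639; adjusted p = 0.34 with an estimated correlation), with the antibody joining chain Jchain at 2.09. Of 5 erythroid genes, 2 rose and 1 fell, also adjusted over the list alone, and camera called the list up (adjusted p = 0.0137; adjusted p = 0.424 with an estimated correlation) with a mean of 0.96 but a median of -0.29. Hba-a2 rose by 6.06 and Hba-a1 had -0.94, copies so alike that the division of their counts is uncertain, and the Hba-a1 call ended without liver 9 (adjusted p = 0.0564), 10 (0.0888), 11 (0.0899), 12 (0.106), 13 (0.121), 15 (0.0912) or 16 (0.0929). Macrophage (median -0.08, adjusted p = 0.951, 1 of 20 rose), T and NK (0.24, 0.954, 0 of 14), neutrophil (-0.01, 0.997, 0 of 8), endothelium (-0.08, 0.997, 0 of 12) and stellate markers (-0.03, 0.997, 1 of 12 rose) did not pass as lists. Adjusted over the list alone, 1 stellate gene was higher and 0 genes of the other lists passed. Adipocyte and pancreas markers had 1 tested member, with a log2 fold change of 0.45, too few for the list test. Cftr had a low level, with a mean FPKM of 0.27 in Ad_GFP_HFLMCD and 0.04 in Ad_Chrebpa_HFLMCD.

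The cell cycle list shifted down in these livers, and stress, matrix and interferon lists had calls that rested on single livers. Of 23 cell cycle genes, 0 rose and 3 fell, with 0 and 8 adjusted over the list alone (median -0.37, adjusted p = 9.86e-05; adjusted p = 0.351 with an estimated correlation and 0.0501 by fry). The replication factor Mcm2 was at -0.84, with its call ended without liver 11 (adjusted p = 0.108), 12 (0.114), 13 (0.111), 15 (0.088) or 16 (0.103). Of 20 endoplasmic reticulum and integrated stress genes, 1 rose and 1 fell, with 2 and 10 adjusted over the list alone (median -0.27, adjusted p = 0.0153; adjusted p = 0.351 with an estimated correlation), and the list call ended without liver 11 (adjusted p = 0.0652) or 15 (0.0501). Of 25 matrix genes, 1 rose and 1 fell, also adjusted over the list alone (median -0.20, adjusted p = 0.0397; adjusted p = 0.769 with an estimated correlation). The collagen Col4a1 was at -0.49, with its call ended without liver 13 (adjusted p = 0.066) or 16 (0.0744), and the list call ended without liver 10 (0.29), 14 (0.347) or 16 (0.157), and without the blocks of clustered calls (0.0578). Of 23 interferon response genes, 1 rose and 0 fell, with 0 adjusted over the list alone (median 0.25, adjusted p = 0.0268; adjusted p = 0.769 with an estimated correlation), and the list call ended without liver 9 (adjusted p = 0.106), 10 (0.0703) or 15 (0.847). Of 22 inflammation genes, 2 rose and 2 fell, also adjusted over the list alone (median 0.02, adjusted p = 0.997), with the monocyte chemokines Ccl7 at -1.48 (SE 0.16, adjusted p = 0.00151) and Ccl2 at -0.78. The p53 list (median -0.08, adjusted p = 0.616, 0 of 16 called, 1 higher and 4 lower adjusted over the list alone) and oxidative phosphorylation (0.01, 0.954, 0 of 20, also adjusted over the list alone) did not pass. On log2(FPKM + 0.1) the medians of the lipid droplet, inflammation and oxidative phosphorylation lists turned negative, at -0.01, -0.10 and -0.07. That fit kept only genes with an FPKM of at least 1 in at least 4 livers, so these medians can cover fewer members.

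Several of the largest differences between the HFLMCD groups were near on-off. Corin, a serine protease gene, fell by 7.45 on the log2 scale (SE 0.18, adjusted p = 1.23e-08), Sectm1b had -6.52 (2.37e-09, mean FPKM 9.74 and 0.10) and Cyp2c39 -6.10 (9.54e-08, mean FPKM 144.8 and 2.02). Akr1c18, a steroid dehydrogenase gene, had -3.75 (adjusted p = 0.0033), while Eno1b, which shares sequence with Eno1 and is uncertain, had -9.58 by edgeR (SE 1.67, 0.0108) without passing limma-voom (0.514). Eno1b was not on-off by group: its FPKM was 183.8, 80.1, 0.37 and 86.0 in livers 9 to 12 and 0.14, 0, 0.30 and 0 in livers 13 to 16, and the log2 fold change was -8.89 without liver 9 and -10.73 without liver 15. In the other direction, Camk2b, a calmodulin-dependent kinase gene, had 6.66 (SE 0.21, adjusted p = 9.54e-08), the histone gene Hist1h2bj 5.44 (0.00129) and Zfp979 2.99 (0.0146), or 2.22 without liver 14. Ppp1r3g, a glycogen-targeting subunit gene of protein phosphatase, had 3.45 (adjusted p = 0.00737, and 0.0521 by limma-voom). The estrogen sulfotransferase gene Sult1e1 was at -2.74 (adjusted p = 0.0287), a call that ended by limma-voom (0.0696) and without liver 9 (0.0501), 11 (0.0626), 13 (0.0796), 15 (0.0711) or 16 (0.0889), with a value of -2.10 without liver 9 and -3.36 without liver 14. Corin lay in a block of 50 tested neighbours on chromosome 5 with 13 calls, and Cyp2c39 and Cyp2c29 in such a block on chromosome 19 with 14. Of the 68 called genes that the rule for naming took, not all of them given here, 36 kept the call without each single liver and 32 lost it without at least 1.

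**Figure D3:**
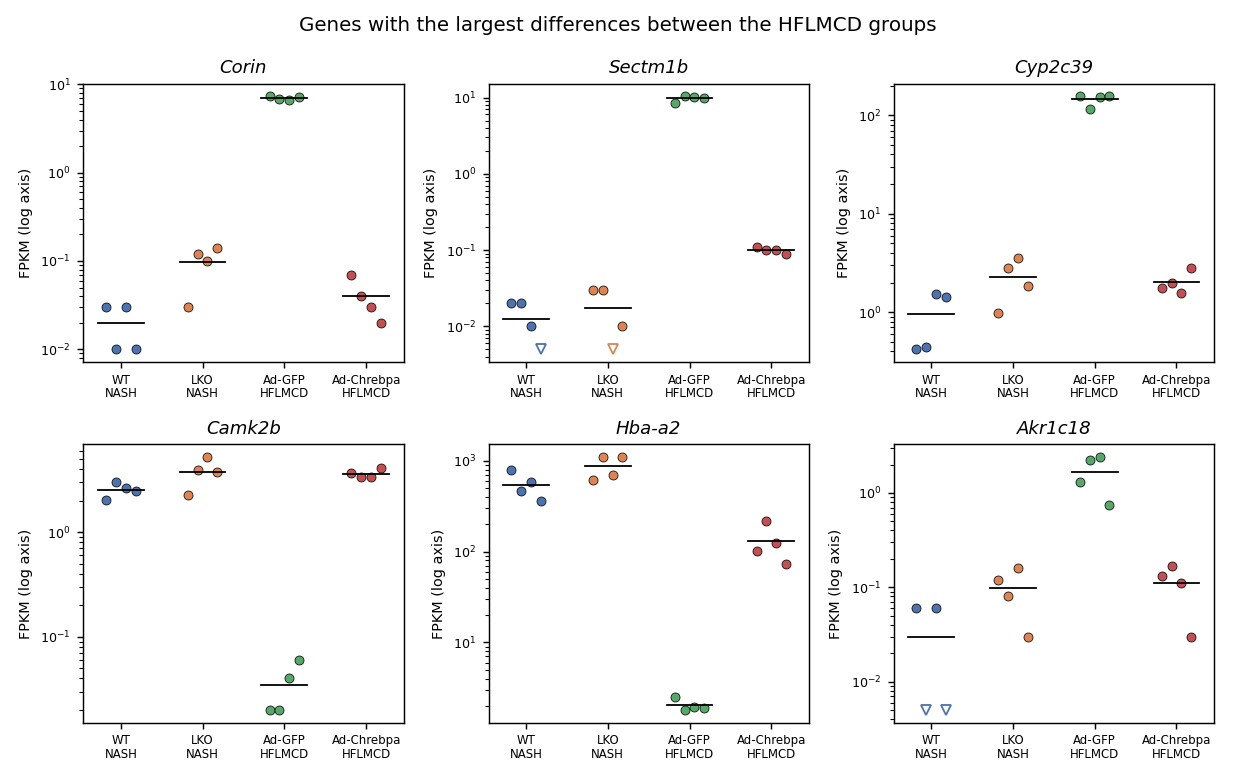
FPKM on a log axis of Corin, Sectm1b, Cyp2c39, Camk2b, Hba-a2 and Akr1c18 in each of the 16 livers by group, with lines for the group mean (n = 4) and open triangles for livers in which the gene was not listed. Mean Corin was 7.01 in Ad_GFP_HFLMCD and 0.04 in Ad_Chrebpa_HFLMCD, and mean Camk2b 0.04 and 3.62.

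Because deletion and overexpression act on 1 gene in opposite directions, their calls were compared over the 12706 genes tested in both. By edgeR 0 genes were called with opposite signs and 0 with the same sign, since the NASH comparison had 0 calls; DESeq2 gave 24 opposite and 18 same, and edgeR without liver 21 gave 34 and 22. At an unadjusted p below 0.05 in each, 296 genes had opposite signs. Of these, 159 were higher with Ad_Chrebpa and lower in LKO_NASH, against 106.1 from the list sizes (Fisher's exact test, two-sided, p = 5.61e-08), and 137 were lower with Ad_Chrebpa and higher in LKO_NASH, against 123.3 (p = 0.176). In the same direction, 108 genes were higher in both, against 138.9 (Fisher's exact test, p = 0.00307), and 80 lower in both, against 94.2 (p = 0.112). Genes are not independent replicates, and the Spearman correlation of the log2 fold changes across genes was -0.02. Several fixed lists passed camera in both comparisons with its preset correlation, though none did with an estimated correlation. Of these, acute-phase and hepatocyte genes had negative medians in LKO_NASH and positive ones in Ad_Chrebpa_HFLMCD, while cell cycle and matrix genes had the reverse. Fatty acid oxidation, interferon response and Nrf2 genes had positive medians in both, and endoplasmic reticulum stress genes negative ones in both. Camera called the erythroid list up in both, with medians of 0.49 and -0.29. Differences between the comparisons were not tested.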

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

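The tests of gene neighbours, of the NASH-diet range, of leaving out other livers, of an exchange of livers and of the Mlxipl intervals were chosen only after the results they bear on were seen, and the position of liver 21 was a test set before.

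Several of the largest differences between Ad_Chrebpa_HFLMCD and Ad_GFP_HFLMCD livers were near on-off, and of these Corin and Cyp2c39 lay among clustered calls. Other large differences, such as Akr1c18 and Hist1h2bj on chromosome 13, lay on chromosomes without any of the 3 densest blocks of calls. Called genes of unlike families sat next to each other in 112 pairs, against 67 to 101 in the middle 95% of 1000 random placements, so a difference in genetic background between the groups of mice is a candidate explanation. Co-regulation of neighbours stays open too, since as many lowest-p genes of the NASH comparison had 128 adjacent pairs (random 78 to 113) and the HFLMCD calls 139 (72 to 106), while for unlike families the NASH number of 96 lay within 73 to 107. Of 23 called genes with a 4-fold or larger difference, 9 had only Ad_GFP_HFLMCD outside the range of the 8 NASH-diet livers, 2 only Ad_Chrebpa_HFLMCD, 6 both and 6 neither, but as the diets differ a response of the Ad_Chrebpa_HFLMCD livers cannot be told apart from a trait of the Ad_GFP_HFLMCD livers. Without the 3 blocks of 50 neighbours with the densest calls (Usp36 to Cenpx on chromosome 11, Stambpl1 to Cyp2c50 on chromosome 19 and Apbb2 to Uba6 on chromosome 5) there were 639 higher and 406 lower calls.

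The NASH comparison called 0 genes with all 8 livers and 420 without liver 21, labelled LKO_NASH. On genes chosen without it, liver 21 had a median position of -0.10 on a scale from the WT_NASH mean at 0 to the mean of the other LKO_NASH livers at 1, so a liver of the WT_NASH kind, from a failed deletion or a wrong label, may be the source. It was not like the WT_NASH livers throughout. On the second principal component, with 21.2% of the variance, liver 21 lay at -32.63, the WT_NASH livers at -8.58 to 34.97 and the other LKO_NASH livers at -19.75 to 10.92. That any left-out liver would raise the count was excluded, since the largest number without another single liver was 0. An exchange with liver 19, labelled WT_NASH, stays open, and Mlxipl does not decide it: on 1525 genes from the other 6 livers, liver 19 lay at 0.52, between what an exchange and its absence would give, and liver 21 at 0.05. On the 420 lowest-p genes chosen without each liver in turn, liver 19 lay at 0.65 and liver 20 of WT_NASH at 0.32. Liver 23 of LKO_NASH lay at 0.47 (quartiles 0.04 to 0.87). For these livers 0 of the genes used passed the adjusted p, and liver 21 was part of the LKO_NASH mean. These positions therefore cannot show whether a middle position is particular to liver 19. Biological variation in diet response among mice was not tested.

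Mlxipl was neither lower in LKO_NASH nor higher in Ad_Chrebpa_HFLMCD livers. A halving of the gene total hidden by noise in LKO_NASH was excluded by the lower 95% bound of -0.54. The upper bound of 0.33 argues against a vector transcript as abundant as Mlxipl and counted as Mlxipl. That holds only if the livers' own Mlxipl transcript did not fall, which a gene total cannot show. It stays open whether the deleted exon is a small part of the counted transcript or the vector sequence was not counted, since the value of 0.05 is a gene total; an exon value was not analysed here.

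In 17 of 256 groups of 4 values, 1 liver lay apart from the other livers of its group by Dixon's ratio at its 95% critical value, where chance gives about 1 in 20, or 12.8. In Ad_GFP_HFLMCD, liver 11 had 243.83 FPKM of Fgf21, 15.83 of Acaca, 506.28 of Apoa5 and 9.32 of Cry2, and liver 10 had 115.36 of Cyp2c39 and 43.34 of Col4a1. In Ad_Chrebpa_HFLMCD, liver 14 had 1.11 FPKM of Sult1e1, liver 15 had 11.57 of Ccl2, and liver 16 had 385.82 of Calr. In WT_NASH, liver 20 had 9.90 FPKM of Fgf21 and 1.65 of Gbp3, liver 18 had 42.19 of Acot1, liver 17 had 1670.63 of Itih4 and 0.08 of Cd8a, and liver 19 had 0.49 of Il2rb. In LKO_NASH, liver 21 had 8.01 FPKM of Gbp3 and liver 24 had 14.95 of Col3a1.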

How the results depend on the processing

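Tests without livers 19 and 21, without clustered blocks, with transcript entries kept separate, and of terms under other settings were chosen after seeing the data. In the NASH comparison 90 genes were higher and 68 lower by DESeq2, 86 and 66 with all 16 livers in 1 fit, 621 and 904 without livers 19 and 21, where the T and NK, cell cycle, p53 and erythroid list calls ended, and 0 to 166 and 0 to 254 without single livers, with 0 under the other settings. In the HFLMCD comparison 1102 were higher and 842 lower by DESeq2, 435 and 997 on log2(FPKM + 1), 430 and 1003 on log2(FPKM + 0.1), 360 and 825 on log2(FPKM + 1) without a filter, 236 and 100 with all 16 livers in 1 fit, 237 and 207 with a fold change of at least 1.5, and 263 to 937 and 137 to 785 without single livers. Of the lists, 0 and 0 passed with an estimated correlation and 0 and 12 by fry. Opposite calls numbered 296 at an unadjusted p below 0.05, 24 by DESeq2 and 0 to 34 without single livers. Terms passing numbered 9 by DESeq2 and 0 to 17 without single livers. For genes not called in the NASH comparison the sign turned: Srebf1 had 0.01 by limma-voom, 0.12 on log2(FPKM + 1) and -0.40 to 0.22 without single livers, Pklr 0.63, 0.66 and -0.45 to 0.42, Mlxipl -0.10 to 0.21, Txnip -0.07 to 0.34 and Fgf21 -0.01 to 1.14. A stricter limit lowers a count by construction; for the other settings, those with fewer livers included, the cause was not tested. Of 68 HFLMCD calls that the rule for naming took, 34 held both without each single liver and under the 4 other settings tried for single genes. Those settings included DESeq2, limma-voom and log2(FPKM + 1), and were not all of the alternatives above. In the NASH comparison 9 of 52 such genes were called without liver 21 and 11 by DESeq2. No paired analysis was possible because the groups share no replicate numbers. In simulated data 55.1% of 2-fold changes were found in the NASH comparison and 83.7% in the HFLMCD comparison. The simulation left out the correlation between genes seen in these livers, so these shares need not hold for the real comparisons.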

Other observations

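Under other settings, tests of terms were chosen only after the results were seen. Among the 676 genes higher in Ad_Chrebpa_HFLMCD livers, fibrinolysis, the breakdown of blood clots, passed as a Gene Ontology process: 6 of its 13 tested genes were called, against 0.6 by chance (one-sided Fisher's exact test, adjusted p = 0.0295). These were the fibrinogen chains Fga, Fgb and Fgg, the plasma proteins Hrg and Plg, and the protease inhibitor Serping1, singled out after their values were seen. The next process, the epoxygenase P450 pathway, had 6 of 17 genes called and did not pass (adjusted p = 0.0898), with the Cyp2c members Cyp2c29, Cyp2c50, Cyp2c54 and Cyp2c68 among the 6. Among the lower genes 0 of 1615 processes passed, and muscle contraction had the lowest adjusted p at 0.17. The number of passing processes was 0 without liver 10, 12 or 13, 3 without liver 9 or 16, 4 without liver 15 and 17 without liver 14.

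Within WT_NASH, Pklr had 26.9, 39.4, 293 and 257 FPKM in livers 17, 18, 19 and 20, and Srebf1 29.9, 84.8, 149 and 99.96. In LKO_NASH livers 21 to 24, Pklr had 126, 117, 194 and 182 FPKM and Srebf1 42.9, 96.3, 135 and 96.5.

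The 8 livers of each experiment can be divided into groups of 4 and 4 in 35 ways, the real one included. In the HFLMCD experiment 1 of the 35 splits, the real one, gave as many as 1110 called genes, and the highest other gave 2. For gene lists 1 of the 35, again the real one, gave as many as 20, and the others gave 6 to 18. Being the only such split is the most that 35 splits can show, so chance division was unlikely for the number of called genes. The number of lists exceeded the others narrowly, so it lends little weight to single list calls. In the NASH experiment 35 of the 35 splits gave at least the real 0 genes, which a count of 0 makes certain, so this cannot test chance division. The highest other split gave 1525, with livers 17, 18, 20 and 21 on one side. That split was singled out as the highest after all were seen, and what divides the livers in this way stays open. For NASH gene lists 8 of the 35 splits gave as many as 15, and the highest other 20, so chance division is not excluded for the number of lists. The correlation of fold changes between the experiments, -0.02, was as far from 0 in 80 of 100 regroupings, and the largest other was 0.388 in size.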
